A study of Streptomyces chattanoogensis with 6 samples.

How the data were processed

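The series measured transcript levels in mycelium of Streptomyces chattanoogensis L10, a filamentous soil bacterium that makes the antifungal natamycin. RNA of the wild type was compared with RNA of a strain lacking scnA and scnB, ABC transporter genes of the natamycin gene cluster studied for their part in exporting the compound. Per the labels, the mycelium came from 48 h of liquid culture at 30 °C in YEME and was in exponential phase. Each genotype had 3 arrays, each with a code of unstated meaning in its title, and the labels do not say that these were separate cultures, so the p-values measure the spread between these samples, which may be technical. All 6 arrays lay on 1 slide and carried 1 scan time, so slide and scan could not act as batches. The row of the slide could: replicate 1 of both genotypes lay in the first row and the other 4 arrays in the second.

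Per the file headers, the deposited scanner files are 1-colour Agilent arrays with Cy3-labelled RNA, read with Feature Extraction 10.7.3.1 (Feature Extraction 10.7 per the submitters' processing notes). Their values are spot intensities on a linear scale; per the file headers, the processed intensity had its background subtracted and was detrended within each array, and nothing was done to make arrays comparable. The deposited table of the authors' processed values was on the log2 scale, as its comparison with the scanner files showed. Its median was 5.27 in every column, and it correlated at r = 0.9999, across probes, with quantile-normalised log2 intensity of the same array, with no difference above 0.49. How the authors made that table is not given in the sources used here, and its exact centring stays unknown.

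The arrays held 15173 spots of 8173 probes once control spots were left out. Of these, 7401 probes were named for a numbered open reading frame (ORF), 1 per ORF, with numbers up to 8117, the number of protein-coding genes given in the design text. A further 700 probes carried only a probe number and were printed as 11 spots each. The last 72 probes were named for contigs and were kept out of the main test. The files pair none of these IDs with a gene symbol or product, so scnA, scnB and the gene lists written beforehand could not be looked up, and the deleted genes could not serve as a check of the labels by name. No list was tested.

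Spots marked by the scanner software as non-uniform or population outliers were left out, and the spots of a probe were averaged on the log2 scale. Each array's 75th percentile over all non-control probes was then subtracted, and levels are given on that scale. An ORF or probe was tested when it was well above background on at least 3 of the 6 arrays, which left 7108. The genotypes were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment over the 7108 and a threshold of 0.05. The words rose, fell and changed are used for results past that threshold. Where a probe was above background on none of the arrays of a genotype, its fold change is given as a bound. The bound sets the mean of the brighter genotype against the mean, over the dimmer arrays, of the higher of the probe's own signal and the lowest signal of any probe well above background.

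The rule for named genes, written before the data were examined, fell back on the 2 IDs with the largest measured log2 rise and the 2 with the largest fall among changed ORFs whose deletion arrays all lay beyond the wild-type arrays, because no names were given. The groupings of ORFs and probes by number were chosen after the data were seen. A run was a stretch of at least 3 consecutively numbered ORFs that all rose or all fell, set against 1000 shuffles of the results over the tested ORFs. Runs were also counted over all probes in the order of their probe numbers, and changed probes of 1 direction within 10 probe numbers of each other were counted once as a group. Windows of 10 consecutive numbers with at least 5 tested ORFs were tested with camera at its preset correlation of 0.01, and again with an estimated correlation. Whether the ORFs of a window moved on balance in 1 direction, which does not compare it with other ORFs, was tested with fry. The plots were drawn with matplotlib 3.10.9 in Python 3.11.15.

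The alternatives were normexp background correction with an offset of 50 (on median spot and background signals), quantile normalisation, scaling to the median, the authors' values, no filter, a filter on all 6 arrays, an intensity trend with robust hyperparameters, array weights, the replicate number or the slide row as a block, and each array left out. Chosen after the data were seen were a fit on the second slide row alone, a floor of 16 units, the contig probes kept in the test, windows shifted by 5 numbers, the share of rises among numbered ORFs alone, and the flanks of the pair under each setting and up to 10 numbers away.

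The test was checked on simulated data with the spread of this comparison, 7108 genes and 200 changed genes, in 20 repeats. It recovered 1.1% of changes of 0.5 on the log2 scale, 41.2% of changes of 1, 80.4% of changes of 2 and 98.1% of changes of 4, and 5.31% of its calls were false. On 500 simulated windows it recovered 10 of 10 shifted by 1 on the log2 scale and called 0 others. On the arrays, 0 of the 31 windows called at the preset correlation passed with an estimated one. These simulated error rates may therefore not carry over to the arrays. The number of arrays limits the precision of every value.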

Results

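Transcript levels were measured on 6 arrays, 3 of wild-type S. chattanoogensis L10 and 3 of the strain lacking scnA and scnB, to profile how the loss of this transporter gene pair alters expression. The median processed signal of the arrays lay between 40.7 and 47.5 units, and no spot was saturated. Between 76.9% and 86.6% of the ORFs and unnumbered probes were well above background on the wild-type arrays. The shares on the deletion arrays were 86.4%, 98.3% and 82.3% for replicates 1, 2 and 3. Dim probes were brighter on deletion replicate 2, where the 5th percentile of the signal was 12.9 units. It was 7.02 on deletion replicate 3 and 2.88 to 4.73 on the rest.

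The largest falls in the deletion strain were those of 2 adjacent ORFs, and the 2 ORFs named for their measured rise lay within 1 run of neighbours. L10.orf5181 fell 29.6-fold, from a level of 2.81 ± 0.16 (SD, n = 3) in the wild type to -2.08 ± 0.23 (n = 3) in the deletion, a log2 fold change of -4.89 (SE 0.18, adjusted p = 0.000275). L10.orf5182 fell 9.85-fold, from 0.97 ± 0.06 to -2.33 ± 0.33, a log2 fold change of -3.30 (SE 0.20, adjusted p = 0.00343). L10.orf2287 rose at least 6.18-fold (adjusted p = 0.00428): it was above background on 0 of 3 wild-type arrays, with a measured level of -5.29 ± 0.24, and on all 3 deletion arrays, at -1.15 ± 0.62. That bound is smaller than the change of L10.orf2285, so these 2 rises have no order. L10.orf2285 rose 13.1-fold, from -3.62 ± 0.24, with 2 of 3 wild-type arrays above background, to 0.09 ± 0.67, a log2 fold change of 3.71 (SE 0.34, adjusted p = 0.00731). Its adjusted p was 0.0525, 0.0526 and 0.0602 without wild-type replicates 1, 2 and 3 in turn, and 0.0713 without deletion replicate 3. Normexp with its offset of 50 gave smaller log2 fold changes that passed the threshold, at -3.42, -1.87, 1.01 and 1.64 for L10.orf5181, L10.orf5182, L10.orf2287 and L10.orf2285, and a floor of 16 units gave 1.76 and 3.01 for the last 2. The files do not pair these IDs with gene names, so none of them can be set against scnA or scnB by name.

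The ORFs numbered next to the pair showed no fall of that size. The signal of L10.orf5181 was 875 to 901 units on the wild-type arrays and 24.0 to 31.0 on the deletion arrays, and that of L10.orf5182 was 216 to 285 against 20.1 to 26.7. Both stayed well above background on all 3 deletion arrays. Of the 10 ORFs flanking the pair, 5 on each side and with wild-type levels of 2.05 to 4.99, 0 passed the limma test and 0 had an unadjusted p under 0.05. Their log2 fold changes ran from -0.42 to 0.03 with a median of -0.20, the smallest adjusted p was 0.398, and the 95% bounds of the single ORFs reached from -1.07 to 0.60. These values depended on the deletion arrays: without deletion replicate 1, 9 of the 10 fell, with log2 fold changes of -0.71 to -0.21 and a median of -0.47, whereas the medians were -0.11 and -0.07 without deletion replicates 2 and 3, with 0 passing. Array weights gave 9 falls and the second slide row alone 3. The flanks also varied with the normalisation, with 0 passing: the median was -0.31 with quantile normalisation and -0.32 with the authors' values or after scaling to the median. In these 3 settings 3, 4 and 0 of the 10 had an unadjusted limma p under 0.05. The 10 ORFs that lay 6 to 10 numbers away had a median of -0.74 (-1.03 to 1.37), of which 0 passed and 7 had an unadjusted p under 0.05. Normexp and the intensity trend with robust hyperparameters each gave 3 falls among these 10, and quantile normalisation and the authors' values 1 each. Without deletion replicate 1, 7 of these fell and 1 rose, with a median of -0.99 and a range of -1.41 to 2.04, while L10.orf5181 and L10.orf5182 stood at -4.80 and -3.12. Among 5600 pairs of adjacent tested ORFs, this was the 1 pair in which both fell by 3 or more on the log2 scale. Only these 2 ORFs fell that far, so no other pair was possible and the count restates that they are adjacent.

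**Figure D1:**
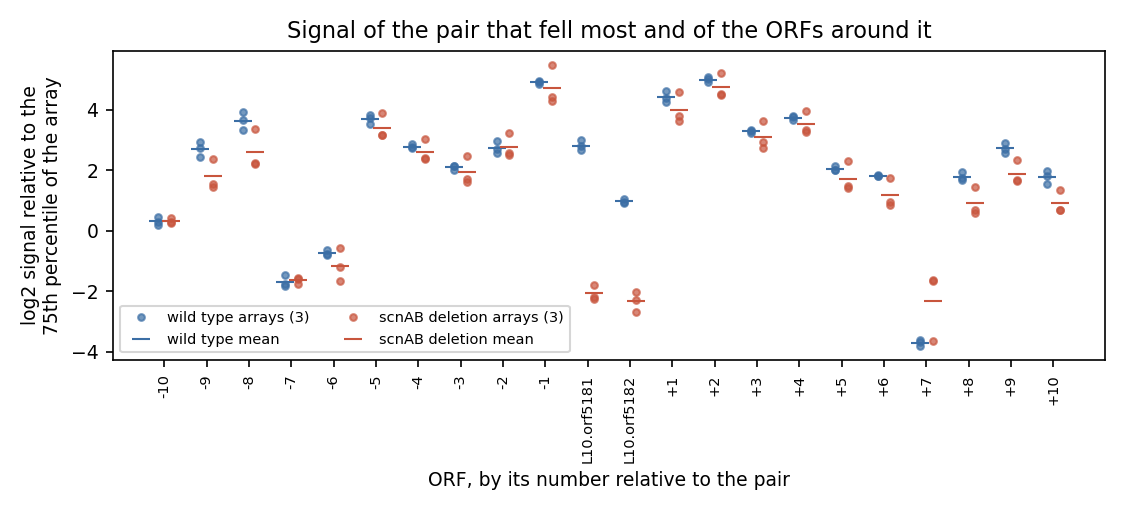
Log2 signal relative to the 75th percentile of the array (y axis) for L10.orf5181, L10.orf5182 and the 10 ORFs numbered before and after them (x axis). Points are single arrays, 3 of the wild type in blue and 3 of the deletion in red, and bars are group means. The pair lies at 2.81 and 0.97 in the wild type and at -2.08 and -2.33 in the deletion, whereas the nearest 5 ORFs on either side differ by -0.42 to 0.03 and the next 5 by -1.03 to 1.37.

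Across the array, 202 of 7108 tested ORFs and probes changed, 140 higher and 62 lower in the deletion. Of these, 154 changed at least 2-fold, 102 upward and 52 downward. All 202 had deletion arrays that lay wholly beyond the wild-type arrays. The same held for 1937 of those tested, or 27.3%, where arrays that differ only at random give 10% on average. ORFs vary together and share the median shift given below, so this excess is no test of the genotype. At an unadjusted p under 0.05 there were 1499. The excess of rises varied with the processing: 69.3% of the changes were rises here, against 64.5% after scaling to the median (98 higher, 54 lower) and 54.8% with quantile normalisation (245 higher, 202 lower). The share was 54.8% with the authors' values (250 higher, 206 lower) and 57.7% with normexp background correction (259 higher, 190 lower). Among numbered ORFs alone it was 63.7% here, 57.1% after scaling to the median and 51.1% both with quantile normalisation and with the authors' values. The median log2 fold change of all tested ORFs and probes was 0.14 here, -0.01 with quantile normalisation and 0.03 after scaling to the median, so changes are to be read relative to that shift. With the tested ORFs and probes split by mean level into 4 groups of 1777, it was 0.42 in the lowest group, where 11 rose and 2 fell, and -0.03 in the highest, where 65 rose and 25 fell. The count depended on single arrays: it was 10, 6 and 13 without wild-type replicates 1, 2 and 3, and 2343, 33 and 10 without deletion replicates 1, 2 and 3. The count of at least 2-fold changes was 10, 6 and 13 and then 813, 33 and 10 in the same order. All 202 were still called without deletion replicate 1. With the slide row as a block 180 changed, and within the second row alone 1915 did. The first row held 1 array of each genotype and allowed no test.

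**Figure D2:**
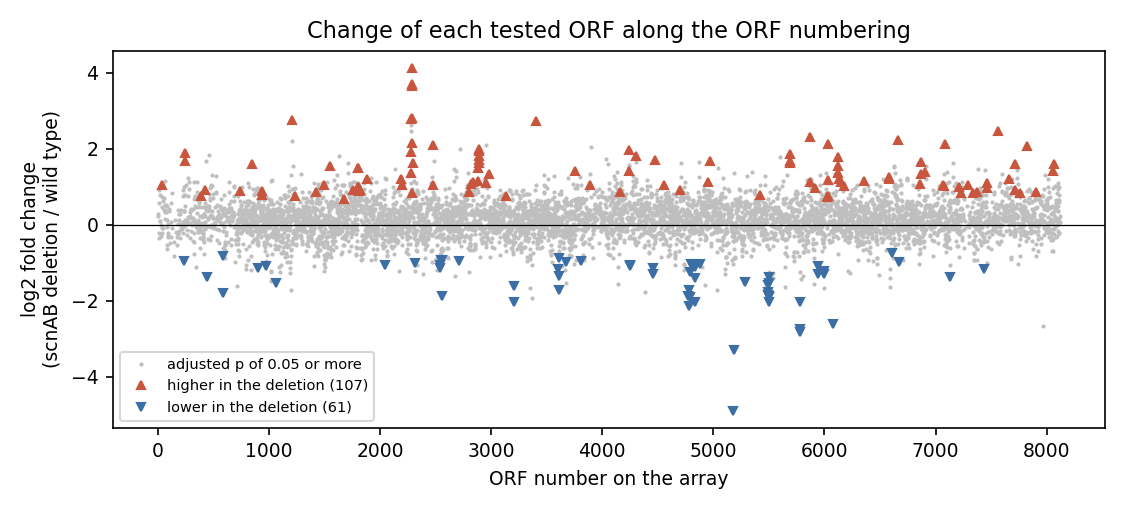
Log2 fold change between the scnAB deletion and the wild type (y axis) of each tested numbered ORF against its number on the array (x axis). Grey dots did not pass the threshold, red triangles mark ORFs that rose and blue triangles the 61 that fell. The lowest point is L10.orf5181 at -4.89, and L10.orf2285 stands at 3.71.

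Changed ORFs lay next to one another far more often than in shuffled data. Of the 168 numbered ORFs that changed, 41 fell into 11 runs of at least 3 consecutive numbers, 24 of them in 6 runs that rose and 17 in 5 runs that fell. Shuffling gave a mean of 0.084 ORFs in runs and at most 3 in 1000 shuffles (permutation p = 0.001, the smallest these can give). The strongest run was 5 ORFs that rose, L10.orf2285 and L10.orf2287 among them. Its mean log2 fold change was 3.29, or 2.75 with the 2 ORFs that were above background on no wild-type array set at their bound. The strongest run downward was 3 ORFs with a mean of -2.53, from a wild-type level of 3.08 to 0.55 in the deletion. The longest run of numbered ORFs held 6, all above background on every wild-type array, which rose by a mean of 1.71. Its mean level was 1.89, 1.89 and 1.87 on deletion replicates 1, 2 and 3, against 0.23, 0.09 and 0.20 on the wild-type replicates. The other 3 runs of 3 that fell had means of -1.73, -1.61 and -1.51, and a run of 5 that fell had a mean of -1.74. The remaining runs that rose had means of 2.02, 1.73 and 1.35 for 3 ORFs each and 1.20 for 4 ORFs, the last 1.03 with 1 ORF at its bound. Without wild-type replicates 1, 2 and 3 the runs held 0, 0 and 3 ORFs, and without deletion replicates 1, 2 and 3 they held 548, 12 and 3.

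**Figure D3:**
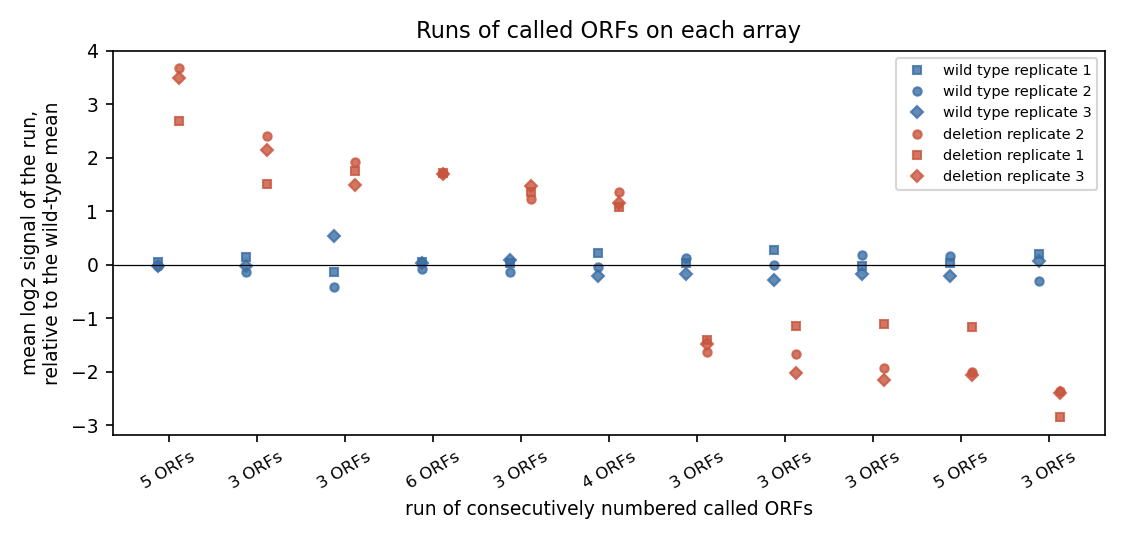
Mean log2 signal of each of the 11 runs on each array, relative to the wild-type mean of the run (y axis), with the runs ordered from the largest rise to the largest fall and labelled by their number of ORFs (x axis). Blue marks are wild-type and red marks deletion arrays, with a shape for each replicate number. The runs range from a mean of 3.29 to -2.53, and in the run of 6 ORFs the 3 deletion arrays lie on top of one another.

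Windows of 10 consecutive numbers gave a broader view of the same order. Of 750 windows, 31 shifted with camera at its preset correlation, 8 upward and 23 downward relative to all other ORFs, but 0 passed with an estimated correlation (adjusted p = 0.999 for each of the 31), where 22 windows had an unadjusted p under 0.05. At the preset correlation, with quantile normalisation and with the authors' values the split was 11 upward and 16 downward, and after scaling to the median it was 8 and 14. Tested with fry against no change, rather than against other ORFs, 1 window passed and 113 had an unadjusted p under 0.05. Neighbouring ORFs also had related values in general: across 5600 adjacent pairs the log2 fold changes correlated at r = 0.404 and the wild-type levels at r = 0.362, against at most 0.045 and 0.039 in 200 shuffles. These correlations are across ORFs, which are not independent replicates.

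The deletion arrays differed from one another more than the wild-type arrays did. The median SD of an ORF or probe between replicates was 0.32 in the deletion and 0.16 in the wild type, and it was larger in the deletion for 77.2% of those tested. Across tested ORFs, the wild-type arrays correlated with each other at r = 0.980 to 0.983, and deletion replicates 2 and 3 at 0.984. Deletion replicate 1 correlated with replicates 2 and 3 at 0.950 and with the wild-type arrays at 0.962 to 0.963. The mean of deletion replicates 2 and 3, both in the second slide row, lay at least 2-fold from the mean of all 3 wild-type arrays for 962 ORFs and probes. Deletion replicate 1, in the first row, lay on the same side for 69.1% of them and at least 2-fold off on that side for 14.3%. Of the 202 that changed, 123 were at least 2-fold off on that side in deletion replicate 1. The 202 were called in a fit that included deletion replicate 1, so this count is no independent check. L10.orf5181 stood in deletion replicate 1 at 3.01% of its wild-type level and L10.orf5182 at 7.96%.

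**Figure D4:**
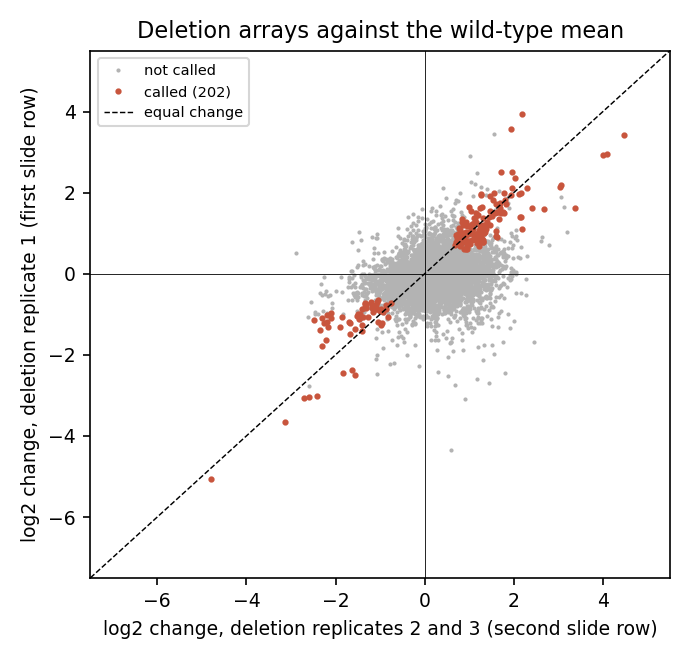
Log2 change from the wild-type mean in deletion replicate 1, the deletion array in the first slide row (y axis), against the mean change in deletion replicates 2 and 3 of the second row (x axis), for each tested ORF and probe. Red points are the 202 that changed, grey points the rest, and the dashed line marks equal change. The slope through the red points was 0.868, and that through the 962 points at least 2-fold off in replicates 2 and 3 was 0.272. Both slopes depend on the choice of points. Replicate 1 was in the fit that called the red points, whereas the 962 were chosen by replicates 2 and 3 alone.

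The longest run that rose, in the order of probe numbers, consisted of probes without an ORF number. The probe numbers of the numbered ORFs follow the ORF order, with 0 out of place, so all probes could be put in 1 order. In that order 21 consecutive unnumbered probes rose together, all above background on all 6 arrays, with log2 fold changes of 0.89 to 1.38 and a mean of 1.18. Their mean level lay between 3.35 and 3.42 on the wild-type arrays and between 4.39 and 4.70 on the deletion arrays. Of the 34 unnumbered probes that changed, 27 were among the 40 tested within 25 numbers of the middle of this run, and all 27 rose. Elsewhere 7 of 535 changed, or 1.31%, 6 of them higher. Of 6533 numbered ORFs, 168 changed, or 2.57%, of which 63.7% were higher. Over all probes, runs of at least 3 held 72 probes, against at most 6 in 1000 shuffles (permutation p = 0.001, the smallest these can give). These counts in probe order were made after the data were seen. All 21 kept a positive change without each array in turn. However, 0 of 21 passed without wild-type replicates 1, 2 or 3 or deletion replicates 2 or 3, and 21 passed without deletion replicate 1.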

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

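Of the settings below, the second slide row, the floor, the contig probes and all settings for runs and windows were chosen after the data were seen. L10.orf5181 and L10.orf5182 kept their direction and stayed past the threshold in all 19 alternatives, at -5.13 to -3.42 and -3.58 to -1.87, and L10.orf2287 in all 18 that tested it, at 1.01 to 4.48. L10.orf2285 kept its direction in 18 and passed in 13. Its adjusted p ran from 7.14e-05 to 0.0874. The count of 202 became 449 with normexp, 447 with quantile normalisation, 456 with the authors' values, 364 with the filter on all 6 arrays, 506 with an intensity trend and robust hyperparameters, 3197 with array weights, 1915 in the second slide row alone and 81 with no filter. In that order of settings the ORFs in runs, 41 in the main result, numbered 97, 102, 105, 73, 126, 909, 394 and 15. The 154 changes of at least 2-fold became 236 with the authors' values, 238 with the trend, 770 with array weights, 907 in the second row and 76 with no filter. Leaving out each array in turn gave 6 to 2343 changes (lowest without wild-type replicate 2, highest without deletion replicate 1), 6 to 813 of at least 2-fold and 0 to 548 ORFs in runs. The array weights were 0.136 for deletion replicate 1 and 4.32 for deletion replicate 3. Leaving out an array leaves fewer samples, which does not account for the higher counts without deletion replicate 1. The cause was not tested for those counts or for the other settings. All 202 kept their sign under each setting, except that the filter on all 6 arrays tested 187 of them. The 31 windows became 0 with an estimated correlation, and stayed between 22 and 37 under the other settings.

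With the replicate number as a block 4 ORFs or probes changed, all 4 at least 2-fold, and 0 lay in runs. The deviations of same-numbered arrays correlated at -0.223, -0.260 and 0.063 for replicates 1, 2 and 3, and not every array correlated best with its own number. These values gave no sign that the numbers pair arrays. With 3 arrays in each genotype they cannot exclude it. The brightest probe of a gene was not run, as each ORF had 1 probe, and neither were the alternatives for scnA, scnB and the gene lists, which matched no ID. For the 4 ORFs and probes that rose and were well above background on no wild-type array, the signal allows a bound only.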

Other observations

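The tests on wild-type RNA, the identity of the pair, the splits of the arrays, the shuffled runs, scaling to the median as a test of the rises, the counting of neighbours as 1 group, the numbered ORFs alone and the flanks under other settings were chosen only after the results were seen, as were the contig probes and the stretches by size.

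Longer stretches appeared when ORFs were joined by size alone, at least 2-fold in 1 direction over at least 4 consecutive numbers. The longest held 15 ORFs with a mean log2 fold change of -1.75, all above background on every wild-type array, of which 8 fell past the threshold. The next held 12 ORFs with a mean of 2.61, or 2.22 with the 4 ORFs above background on no wild-type array set at their bound, of which 8 rose. It takes in the run with L10.orf2285 and L10.orf2287. Of the 72 probes named for 18 contigs, 34 of 36 forward and 25 of 36 reverse probes were above background on at least 3 arrays. When they were tested with limma along with the ORFs, 0 of 59 changed and 5 had an unadjusted p under 0.05. Their smallest adjusted p was 0.148 and their median log2 fold change 0.16.

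Placement by chance along the numbering does not account for the runs, since 0 of 1000 shuffles put as many as 41 ORFs in runs and the highest held 3. Neighbouring ORFs also had related wild-type levels (r = 0.362), so runs can form whatever made the ORFs change. The shuffles do not link the runs to the genotype. For the count of 202, 1 of the 10 splits of the 6 arrays into 3 and 3 gave as many, the real one itself, and the highest other gave 0. Splits of 3 against 3 are too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1499 and the highest other 1369, with wild-type replicate 1 beside deletion replicates 2 and 3.

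More ORFs and probes rose than fell, 140 against 62, and among the 168 numbered ORFs 63.7% of the changes were rises. A constant offset from the 75th percentile would leave no excess after scaling to the median. There 64.5% of all 152 changes were rises (exact binomial 95% interval 56.3 to 72.1). Of the 126 changes of numbered ORFs, 57.1% were rises (interval 48.0 to 65.9). Changes of 1 direction within 10 probe numbers were also counted once. The share was then 62.8% for numbered ORFs (interval 51.1 to 73.5) and 63.3% for all changes (interval 51.7 to 73.9). Raised signal of dim probes on deletion replicate 2 would leave no excess above the median level. There 65.8% of all 155 changes were rises, which met the limit of 60% set beforehand for a source other than dim probes. The interval of 57.8 to 73.2 reached under 60, but the limit had been set for the share and not for its interval. Of the 122 changes of numbered ORFs, 57.4% were rises (interval 48.1 to 66.3). With neighbours counted once, numbered ORFs gave 63.3% (interval 51.7 to 73.9) and all changes 64.6% (interval 53.3 to 74.9). Without deletion replicate 2, 25 of 33 changes were rises, or 75.8% (interval 57.7 to 88.9). With neighbours counted once the share was 73.7% (interval 48.8 to 90.9). Without that array the median log2 fold change of all tested ORFs and probes was 0.05, against 0.14 with it. Quantile normalisation also evens out the shape of the distributions. With it, 54.8% of all 447 changes were rises (interval 50.1 to 59.5), and 51.1% of the 393 of numbered ORFs (interval 46.1 to 56.2). With neighbours counted once, both shares were 54.3% (intervals 47.7 to 60.8 and 47.5 to 60.9). These intervals include 50 or leave it out depending on how neighbours are counted and on the normalisation. They also treat changes, or groups of neighbours, as independent, although all come from the same arrays and share any shift of a whole array. The intervals therefore do not measure the spread between arrays, and an interval wholly above 50 would not separate the sources either. Scaling, dim probes and the genotype thus cannot be told apart as the source.

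Deletion replicate 1 lay apart from deletion replicates 2 and 3. An effect of the first slide row shared by both genotypes would make wild-type replicate 1, in the same row, deviate alike. The deviations correlated at -0.223 over 7108 ORFs and probes, so they were not alike. Arrays of different rows gave values as far from 0, however. These were 0.266 for wild-type replicate 1 with deletion replicate 2 and 0.247 for wild-type replicate 2 with deletion replicate 1. A correlation of this size therefore cannot decide on a shared effect of the row. With 1 array of each genotype in that row, an effect of position, shared or on deletion replicate 1 alone, cannot be excluded. Wild-type RNA mixed into deletion replicate 1 would have to make up about 72.8% to give the slope seen. That share is 1 minus a slope of log2 changes and only approximate, as RNA mixes on the linear scale. L10.orf5181 stood at 3.01% and L10.orf5182 at 7.96% of the wild-type level, which argues against such a mixture. The titles also give each array a code of its own, with a shared beginning for deletion replicates 1 and 3 and another for replicate 2, but do not say what the codes mark. Differences between isolates or cultures, in growth at harvest or in RNA handling remain open, and no biological explanation was tested because each code has 1 array. The 5th percentile of the signal was 3.14 units on deletion replicate 1, against 12.9 and 7.02 on replicates 2 and 3. Replicate 1 lay at least 2-fold below replicates 2 and 3 for 887 ORFs and probes and above them for 221. Raised signal of dim probes on deletion replicates 2 and 3 also remains open and was not tested as a source.

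The 2 ORFs that fell most carry adjacent numbers, and a candidate explanation is that they are the deleted scnA and scnB. The 10 flanking ORFs had a median log2 fold change of -0.20, but without deletion replicate 1 it was -0.47 and 9 of them fell, and the 10 beyond them had a median of -0.74. A smaller fall of the surroundings is thus not excluded, although the lowest of these 20 under any setting was -1.41. The identity cannot be told from these data, because the files give no gene names. L10.orf5182 on deletion replicate 2, at -2.02 against a wild-type mean of 0.97, just missed the 8-fold fall asked of each array. That limit was set after the results were seen, so the narrow miss says little about the identity either way. Both ORFs kept signal above background on the deletion arrays, and whether that is cross-hybridisation, remaining sequence or transcript was not tested.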
